A study of Homo sapiens with 4 samples.

How the data were processed

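Total RNA was extracted from the transduced cells with silica columns and labelled with biotin for Affymetrix arrays, per the labels' protocols. Per the same labels, progenitors were expanded for 6 days and then differentiated in medium with stem cell factor (20 ng/ml), erythropoietin (1 U/ml), interleukin-3 (5 ng/ml), dexamethasone (2 µM) and beta-estradiol (1 µM). They recovered for 24 h after transduction and were cultured for a further 24 h before puromycin selection.

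The authors deposited 1 intensity per probe set and array on a linear scale, for 22277 probe sets on 4 arrays. Which algorithm summarised the probes, corrected the background and normalized the arrays is not given in the sources used here. The deposited intensities had close but not identical quartiles, so some scaling between arrays is possible, and a real shift in total messenger RNA per cell could not be seen on this scale. The series matrix has no detection calls, so the highest reading of the control probe sets for the bacterial tryptophan gene, 122 units, served as a mark of background. Of the genes tested, 1979 had a mean at or under it.

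Probe sets were named from the platform annotation of 2016. It gives 19064 probe sets 1 gene, 1043 several genes and lists no gene for 2108, beside 62 control probe sets. Of the probe sets with 1 gene, 19052 were matched through the gene identifier to the RefSeq gene table, which changed 0 symbols, and 12 kept the annotation's symbol. No gene was named from a probe set with several genes. A gene was represented by the probe set with the highest mean over all 4 arrays, which left 11963 genes. Of the 1849 genes past the test, 800 had more than 1 probe set, 208 of these had a probe set of opposite sign, and in 9 that probe set also passed.

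Intensities were set to at least 16 (110 values were at or under this floor) and log2-transformed, with no further normalization. Groups were compared in R 4.3.3 with limma 3.58.1 (lmFit and eBayes with a variance trend over intensity, two-sided), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The fit had 2 residual degrees of freedom per gene and 6.70 prior degrees of freedom borrowed across genes. Control probe sets stayed out of the gene test and were tested in a fit over all probe sets, with adjustment over the 62 control probe sets. The spike-in scaling and figure used the r2 series, 12 of 24 poly-A and 9 of 18 hybridisation probe sets. Gene lists (29, each with at least 5 measured genes) were compared with all other genes by camera with a preset inter-gene correlation of 0.01, and again by camera with an estimated correlation. Fry tested in addition whether the genes of a list moved, on balance, in 1 direction, without comparing the list with other genes. The lists were globin genes, heme synthesis, iron handling, red cell membrane, erythroid regulators, late erythroid maturation, fetal globin regulation, markers of 6 other cell types, G1/S, G2/M, p53 targets, BCL2 family, interferon response, histone acetylation, reported ZBP-89 targets, GC-box factors, glucocorticoid response, cholesterol synthesis, glycolysis, respiratory chain, ribosomal proteins, protein and amino acid stress, MYC and ribosome biogenesis, and immediate early genes.

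The groups, tests, gene lists, rule for named genes and all alternatives but the crossed pairing and the spike-in scaling were fixed before the data were examined. Named were ZNF148 and its paralogue, the 12 largest rises and 12 largest falls among genes past the test whose groups did not overlap, every measured globin gene, up to 4 members with the smallest p in each list described, and other list members past the test. AZU1, CTSG and ALAS2 were named after their values were seen. XIST, Y-linked genes and genes without a symbol were not named.

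The test was tried on simulated arrays with the real means for the shZBP-89 and empty vector comparison, over 11963 genes with 50 genes changed at each size. The spread of each simulated gene was drawn from the distribution that limma fitted to the data, and was equal in both groups. The test recovered 10% of genes changed by a log2 difference of 0.25, 56% at 0.5, 100% at 1 and 100% at 2, with 10 false calls. Between the real arrays the median absolute log2 difference was 0.077 with empty vector and 0.116 with shZBP-89. The recovery and false calls in the real data may thus differ. A simulated list shifted by 0.3 was called by camera with the preset correlation and not with the estimated correlation, and 0 lists were called without a shift. The simulated genes varied independently, while estimated correlations in the real lists reached 0.58. The simulation thus does not show how often the preset correlation gives false calls of lists whose genes vary together. Alternatives covered the variance trend, filters on dim probe sets, quantile normalization, median centring, the floor, the choice of probe set, the replicate number as a block, a fold threshold and leaving out each array. Control and marker values were summarised in Python 3.11.15 with pandas 2.3.3, and plots used matplotlib 3.10.9.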

Results

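Expression was measured in human primary erythroid progenitors, the precursors of red blood cells, grown from CD34-positive haematopoietic progenitors and collected on day 6 of erythroid differentiation. The cells carried a lentivirus with a short hairpin RNA against the zinc finger transcription factor ZBP-89 (shZBP-89) or the empty vector. Each group had 2 Affymetrix expression arrays, labelled as biological replicates. The labels do not say whether these came from separate donors or cultures, so the p-values measure the spread between these arrays, which may be technical. Median intensity was 279.45 and 279.47 units on the empty vector arrays, and 270.25 and 288.96 units on the shZBP-89 arrays. Across probe sets, Pearson's r of log2 intensity was 0.997 between the empty vector arrays, 0.995 between the shZBP-89 arrays and 0.990 to 0.993 across the groups. The number of arrays, 2 per group, limits the precision of every value below.

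The comparison asked which transcripts differed in erythroid progenitors with the hairpin against ZBP-89. The control was an empty vector, so 2 kinds of effect cannot be told apart. These are effects of less ZBP-89, and effects of carrying a hairpin or of this hairpin on other transcripts. Other targets of the hairpin were not examined. ZBP-89 is encoded by ZNF148, which was measured by 2 probe sets and was lower on both shZBP-89 arrays with each. The brighter probe set read 1896.82 and 1973.3 units with empty vector and 829.6 and 814.72 units with shZBP-89. Its mean fell from 1935 ± 54.1 to 822 ± 10.5 units (SD, n = 2), which left 42.5% of the empty vector level. The log2 difference was −1.23 (SE 0.07, adjusted p = 1.22e-05 in limma). The dimmer probe set fell from 592 ± 43.0 to 184 ± 0.198 units (SD, n = 2), to 31.1% of the empty vector level, with a log2 difference of −1.68. The paralogue ZNF281, which encodes a related zinc finger protein, measured 1040 ± 30.8 units with empty vector and 1191 ± 25.3 units with shZBP-89 (SD, n = 2). Its log2 difference of 0.20 did not pass the test (adjusted p = 0.105 in limma).

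**Figure D1:**
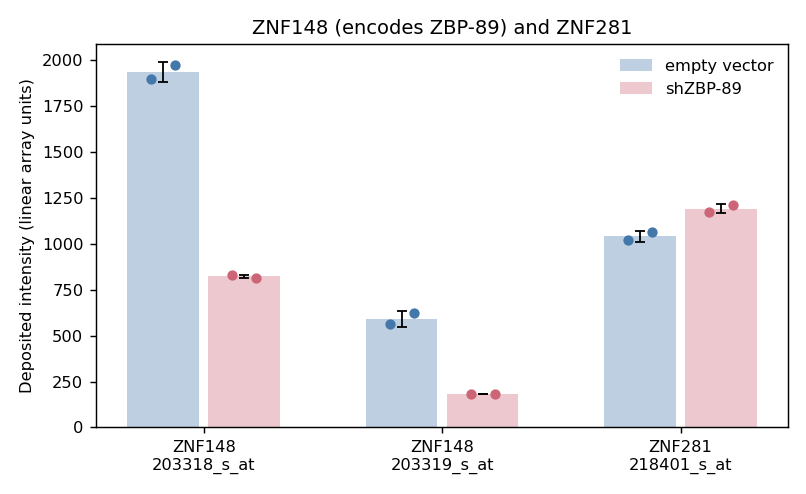
Deposited intensity (linear array units) of the ZNF148 and ZNF281 probe sets with empty vector and shZBP-89; points are arrays, bars are group means and error bars the SD of 2 arrays. Both ZNF148 probe sets lie lower on the shZBP-89 arrays, at 42.5% and 31.1% of the empty vector mean.

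Of 11963 genes tested, 1849 changed at an adjusted p under 0.05 in limma, 986 of them higher and 863 lower with shZBP-89. The differences were mostly small. The median absolute log2 difference of the changed genes was 0.37, and 45 genes rose and 27 fell by 2-fold or more. At an unadjusted p under 0.05 there were 3259 genes. In all 1849 changed genes the shZBP-89 arrays lay on the same side of both empty vector arrays. Over all genes tested this held for 53.6%, where chance gives 33.3%. Leaving out 1 array gave 683 to 4021 genes. The count was 635 genes when limma's variance was fitted without a trend over intensity, and 320 genes when a difference beyond 1.2-fold was required. The split between higher and lower depended on the scaling. With each array scaled to its poly-A spike-in RNAs, the median gene had a log2 difference of −0.40, and 190 genes counted as higher and 9326 as lower. All directions given here are relative to the deposited scale, on which the median gene differed by −0.0029.

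The genes with the largest rises included SLC25A24, which encodes a mitochondrial carrier of ATP-Mg and phosphate. It rose from 68.1 ± 2.02 to 465 ± 21.2 units (SD, n = 2), with a log2 difference of 2.77 (SE 0.11, adjusted p = 3.5e-06 in limma). VIM, which encodes the intermediate filament protein vimentin, rose 4.76-fold from 267 ± 5.06 to 1272 ± 50.8 units (SD, n = 2). MPO, which encodes the granule enzyme myeloperoxidase of granulocytes and their precursors, rose 4.73-fold from 199 ± 28.1 to 936 ± 15.3 units (SD, n = 2). CA1, which encodes the red cell enzyme carbonic anhydrase I, rose by 2.41 on the log2 scale, while its other probe set differed by 0.09. EPAS1, which encodes a hypoxia-inducible factor subunit, and PLCL2, which encodes a phospholipase C-like protein, rose by 2.07 and 2.04, with other probe sets at 0.23 and as low as 0.11. ANXA2, which encodes the membrane-binding protein annexin A2, rose from 2014 ± 63.2 to 6089 ± 120 units (SD, n = 2), and its 3 probe sets gave log2 differences from 1.60 to 1.68. FBN1, which encodes fibrillin-1, rose by 1.88 on the log2 scale with its other probe set at 0.89, and BEX1 rose by 1.57. ROBO1, G0S2 and ALCAM rose by 1.78, 1.76 and 1.63. With empty vector these 3 genes and SLC25A24 lay at or under 122 units, the highest reading of control probe sets for a bacterial gene that human cells lack, so the size of their rise is uncertain.

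The genes with the largest falls included DDIT4, which encodes a stress-induced inhibitor of mTORC1 signalling. It fell 2.63-fold, from 5326 ± 66.9 to 2025 ± 71.4 units (SD, n = 2), with a log2 difference of −1.40 (SE 0.05, adjusted p = 2.78e-06 in limma). DCAF6, which encodes a receptor of cullin ubiquitin ligases, fell 2.78-fold from 4066 ± 26.2 to 1470 ± 172 units (SD, n = 2). MRPL58, which encodes a mitochondrial ribosomal protein, fell 2.73-fold from 2519 ± 3.08 to 923 ± 11.4 units (SD, n = 2). DRAM1, a p53-induced gene of autophagy, had a log2 difference of −1.60, and RCN1, which encodes a calcium-binding protein of the endoplasmic reticulum, −1.34. TUBB2B, a beta-tubulin gene, had −1.27, and HLTF, which encodes a helicase-like factor, −1.24. GDF15, which encodes a secreted protein made by erythroblasts, fell from 7687 ± 20.5 to 3299 ± 206 units (SD, n = 2), while its other probe set differed by −0.19. SMYD2, which encodes a lysine methyltransferase, had −1.68 with the probe set used here and 0.20 with its other probe set. SERPINI1 and ZNF329 had −1.49 and −1.26, and with shZBP-89 both lay within the 122 units of the bacterial control probe sets.

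**Figure D2:**
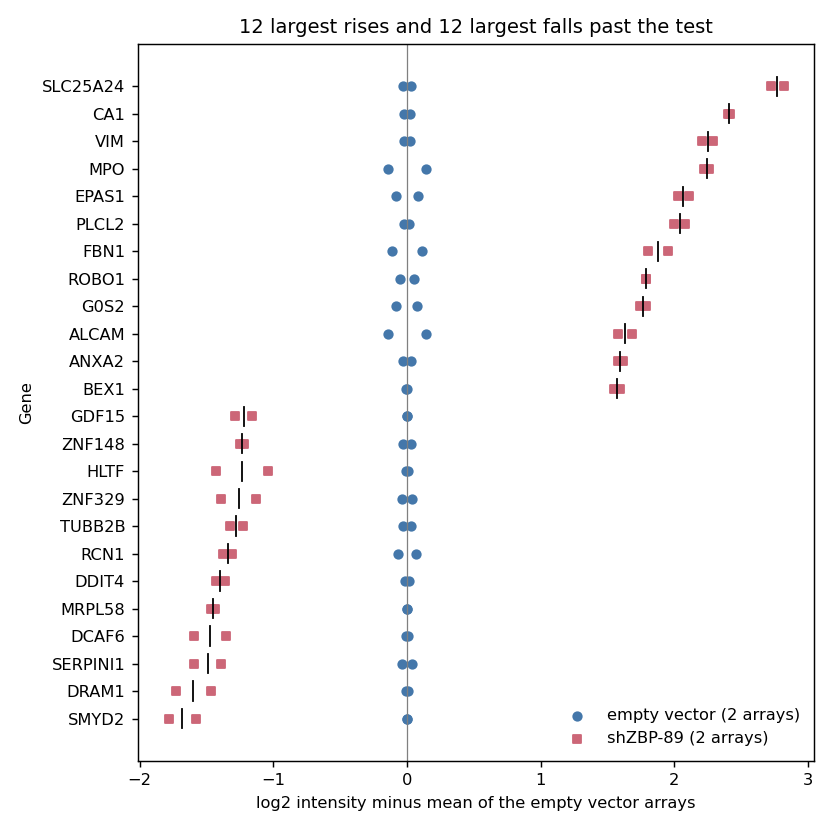
Log2 intensity on each array minus the mean of the empty vector arrays, for the 12 genes with the largest rise and the 12 with the largest fall among those past the test; circles are empty vector arrays, squares shZBP-89 arrays and black lines the shZBP-89 mean. The genes were chosen to have both shZBP-89 arrays on the same side of both empty vector arrays, and their differences run from −1.68 for SMYD2 to 2.77 for SLC25A24.

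Genes of the red cell programme were more often lower than higher. In heme synthesis, 7 of 13 measured genes fell and 0 rose (8 and 0 adjusted over the list alone), with a median log2 difference of −0.18. CPOX, which encodes coproporphyrinogen oxidase, fell from 8833 ± 67.1 to 6124 ± 742 units (SD, n = 2), and SLC25A37, which encodes the mitochondrial iron carrier mitoferrin, from 3766 ± 143 to 2447 ± 542 units. ALAS2, which encodes the erythroid form of the first enzyme of heme synthesis, measured 6191 ± 101 units with empty vector and 6198 ± 221 units with shZBP-89 (SD, n = 2). Its log2 difference of 0.0014 did not pass (adjusted p = 0.99 in limma). The heme synthesis list differed from other genes in limma's camera (adjusted p = 0.000327), with adjusted p = 0.59 with an estimated correlation. In the red cell membrane and blood group list, 12 of 30 genes fell and 3 rose (14 and 4 adjusted over the list alone; median −0.18, camera adjusted p = 0.000192, adjusted p = 0.59 with an estimated correlation). SLC4A1, which encodes the anion exchanger band 3, fell from 10472 ± 141 to 6335 ± 251 units (SD, n = 2). XK and CD47 had log2 differences of −0.47 and −0.45, with other probe sets of CD47 from −0.61 to −0.18, and EPB42, which encodes the membrane skeleton protein 4.2, rose by 0.25. Of 29 erythroid regulators, 11 fell and 3 rose (12 and 3 adjusted over the list alone; median −0.10, camera adjusted p = 0.00178, adjusted p = 0.749 with an estimated correlation). The transcription factor genes GFI1B, FOXO3, BCL11A, GATA1, TAL1 and KLF1 had log2 differences of −0.61, −0.51, −0.49, −0.34, −0.30 and −0.10, with other probe sets of BCL11A up to −0.22 and of TAL1 up to −0.099. The list passed in 14 of 16 alternative fits. NFE2L2, which encodes a regulator of the oxidative stress response, rose by 0.66, and MYB, which encodes a progenitor transcription factor, by 0.22 with its other probe set at 0.097, and the values of MYB and EPB42 turned negative under the poly-A scaling. On the same arrays the granulocyte gene MPO was higher by 2.24 on the log2 scale, and the 5' signal of ACTB control probe sets differed by −0.34.

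Among the 6 globin genes measured by probe sets of their own, including the alpha-globin chaperone gene AHSP, 3 fell and 0 rose (3 and 0 adjusted over the list alone). HBE1, the embryonic epsilon-globin gene, fell from 334 ± 15.1 to 228 ± 5.08 units (SD, n = 2; log2 difference −0.55, and −0.13 with its other probe set), HBD, the delta-globin gene, from 27788 ± 309 to 25492 ± 632 units, and AHSP from 18697 ± 135 to 17691 ± 233 units. HBB, the adult beta-globin gene, measured 52636 ± 536 and 51507 ± 183 units (SD, n = 2) and did not pass the test (adjusted p = 0.152 in limma), at levels next to the highest value on any array, 53015 units. HBZ and HBQ1 had log2 differences of −0.18 and 0.025 and did not pass either. The list had a median log2 difference of −0.10 and a camera adjusted p of 0.0081, with adjusted p = 0.59 with an estimated correlation, and passed in 10 of 16 alternative fits. The annotation gives 9 further probe sets to several alpha-globin or several gamma-globin genes. All 9 fell, by log2 differences from −0.12 to −0.20 (adjusted p 4.72e-05 to 0.00209 in limma), at values of 36825 units or more. The late erythroid maturation list went both ways, with 12 of 35 genes lower and 7 higher (13 and 7 adjusted over the list alone), a median of −0.085 and a mean of −0.0028. GABARAPL2, an autophagy gene, TRIM10 and PRDX2, which encodes a red cell peroxiredoxin, had −0.55, −0.64 and −0.24, with another probe set of TRIM10 at −0.15. CA1 rose by 2.41 with its other probe set at 0.09, and SELENBP1 and GPX1, which encodes a glutathione peroxidase, by 0.91 and 0.54. The camera adjusted p of the list was 0.0486, with adjusted p = 0.627 with an estimated correlation. The call held in 1 of 16 alternative fits with the preset correlation.

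Among genes of the cell cycle and of amino acid and secretory stress more fell than rose, though most did not pass. Of 39 G1/S cell cycle genes 13 fell and 1 rose, UNG (21 and 3 adjusted over the list alone; median −0.14, camera adjusted p = 8.5e-06, adjusted p = 0.627 with an estimated correlation). PRIM1, a DNA primase subunit gene, had a log2 difference of −0.39, CENPU −0.34, and PCNA and MCM4, which encode the replication clamp and a subunit of the replicative helicase, −0.24 each. UNG, which encodes uracil-DNA glycosylase, rose by 0.34 on the deposited scale and had −0.053 under the poly-A scaling. Of 48 G2/M genes 8 fell and 2 rose (10 and 2 adjusted over the list alone; median −0.051, camera adjusted p = 0.0231, adjusted p = 0.759 with an estimated correlation). AURKA, which encodes the mitotic kinase Aurora A, fell from 6365 ± 134 to 4135 ± 327 units (SD, n = 2; its probe sets from −0.65 to −0.24 on the log2 scale), and CDK1 had −0.17. The G2/M call held in 10 of 16 alternative fits, with adjusted p up to 0.74. Of 30 unfolded protein and amino acid stress genes 10 fell and 2 rose (12 and 2 adjusted over the list alone; median −0.12, camera adjusted p = 0.000327, adjusted p = 0.627 with an estimated correlation). XBP1, a transcription factor gene of the unfolded protein response, fell 2.03-fold and the pseudokinase gene TRIB3 2.11-fold. ATF4 and its target genes ASNS, SLC7A5 and DDIT3 had −0.38, −0.48, −0.50 and −0.57. Of 20 immediate early genes 4 fell and 0 rose (4 and 0 adjusted over the list alone; median −0.14, camera adjusted p = 0.00715, adjusted p = 0.59 with an estimated correlation), including DUSP1, which encodes a MAP kinase phosphatase, at −0.72, with another probe set at −0.29, and MYC at −0.33. The stress and immediate early lists each passed in 15 of 16 alternative fits. The 5' signals of the ACTB and GAPDH control probe sets were lower on the same arrays, at −0.34 and −0.27.

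Some genes of other blood lineages rose. Of 22 granulocyte precursor genes 4 rose and 1 fell (5 and 1 adjusted over the list alone; median 0.22, camera adjusted p = 0.00238, adjusted p = 0.627 with an estimated correlation). ELANE, which encodes neutrophil elastase, rose from 345 ± 11.1 to 783 ± 2.02 units (SD, n = 2), FUT4 by 0.93 and MS4A3 by 0.66 on the log2 scale, with another probe set of FUT4 at 0.11 and MS4A3 with empty vector within the 122 units of the bacterial control probe sets. PRTN3, which encodes proteinase 3, had −0.42 and lay close to background. Of 27 megakaryocyte and platelet genes 3 rose and 0 fell (3 and 0 adjusted over the list alone; median 0.069, camera adjusted p = 0.0455, adjusted p = 0.749 with an estimated correlation). These were the platelet chemokine genes PPBP, PF4 and PF4V1, at 1.16, 0.97 and 1.12, of which PF4V1 lay within the same 122 units in both groups. The megakaryocyte call held in 10 of 16 alternative fits, with adjusted p up to 0.569. With arrays scaled to the poly-A spike-ins the granulocyte and megakaryocyte medians were −0.18 and −0.32. Of 26 monocyte and macrophage genes 4 rose and 0 fell (5 and 0 adjusted over the list alone), which were the lysozyme gene LYZ, at 987 ± 56.5 and 1811 ± 121 units (SD, n = 2), and the HLA class II pathway genes CD74, HLA-DPA1 and HLA-DPB1, with another probe set of HLA-DPA1 at 0.27. That list did not pass (median 0.040, camera adjusted p = 0.214). Of 22 mast cell, basophil and eosinophil genes 3 fell, CLC at −0.67, TPSAB1 at −0.43 with other probe sets up to −0.021 and KIT at −0.21, and 1 rose, CPA3 at 0.45 (3 and 1 adjusted over the list alone; camera adjusted p = 0.228). In lymphocyte genes 1 of 23 rose, LEF1 at 0.60 with another of its probe sets at −0.09 (1 adjusted over the list alone; camera adjusted p = 0.813). Of 22 stem and progenitor genes 3 rose, SOX4, CD99 and MECOM, with probe sets of SOX4, CD99 and MECOM down to −0.19, 0.29 and −0.080, and 3 fell, among them KIT and PROM1 (3 and 3 adjusted over the list alone; camera adjusted p = 0.813). On the same arrays the difference between the 3' and 5' signals of ACTB was larger by 0.33 on the log2 scale.

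Genes of cholesterol synthesis, the respiratory chain and the ribosome were more often higher on the deposited scale. Of 18 cholesterol synthesis genes 7 rose and 2 fell (7 and 2 adjusted over the list alone; median 0.11, camera adjusted p = 0.00703, adjusted p = 0.59 with an estimated correlation). LSS, which encodes lanosterol synthase, rose from 1659 ± 87.4 to 2838 ± 162 units (SD, n = 2; its 3 probe sets from 0.12 to 0.77 on the log2 scale), MSMO1 by 0.56 and DHCR7 by 0.41 on the log2 scale, while SQLE, which encodes squalene epoxidase, had −0.26 with other probe sets up to 0.08. Of 59 respiratory chain genes 11 rose and 3 fell (14 and 5 adjusted over the list alone; median 0.042, camera adjusted p = 0.00453, adjusted p = 0.743 with an estimated correlation). NDUFB2, a complex I gene, rose by 0.25 and CYC1, the cytochrome c1 gene, had −0.26. ATP5MC2, an ATP synthase gene, had 0.39 with the probe set used here and −0.29 with its other probe set. Of 51 ribosomal protein genes 10 rose and 0 fell (13 and 0 adjusted over the list alone; median 0.031, camera adjusted p = 0.000327, adjusted p = 0.712 with an estimated correlation), with RPL36 at 0.13. The respiratory chain and ribosomal protein lists each passed in 12 of 16 alternative fits. Without shared probe sets (_x_at and _s_at) the ribosomal protein median was −0.0095, with adjusted p = 0.738, and the respiratory chain had adjusted p = 0.71. With arrays scaled to the poly-A spike-ins the medians of the cholesterol synthesis, respiratory chain and ribosomal protein lists were −0.29, −0.35 and −0.36, and cholesterol synthesis, which passed in 14 of 16 alternative fits, did not pass there (camera adjusted p = 0.169). RPL36 and NDUFB2 also turned negative there.

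**Figure D3:**
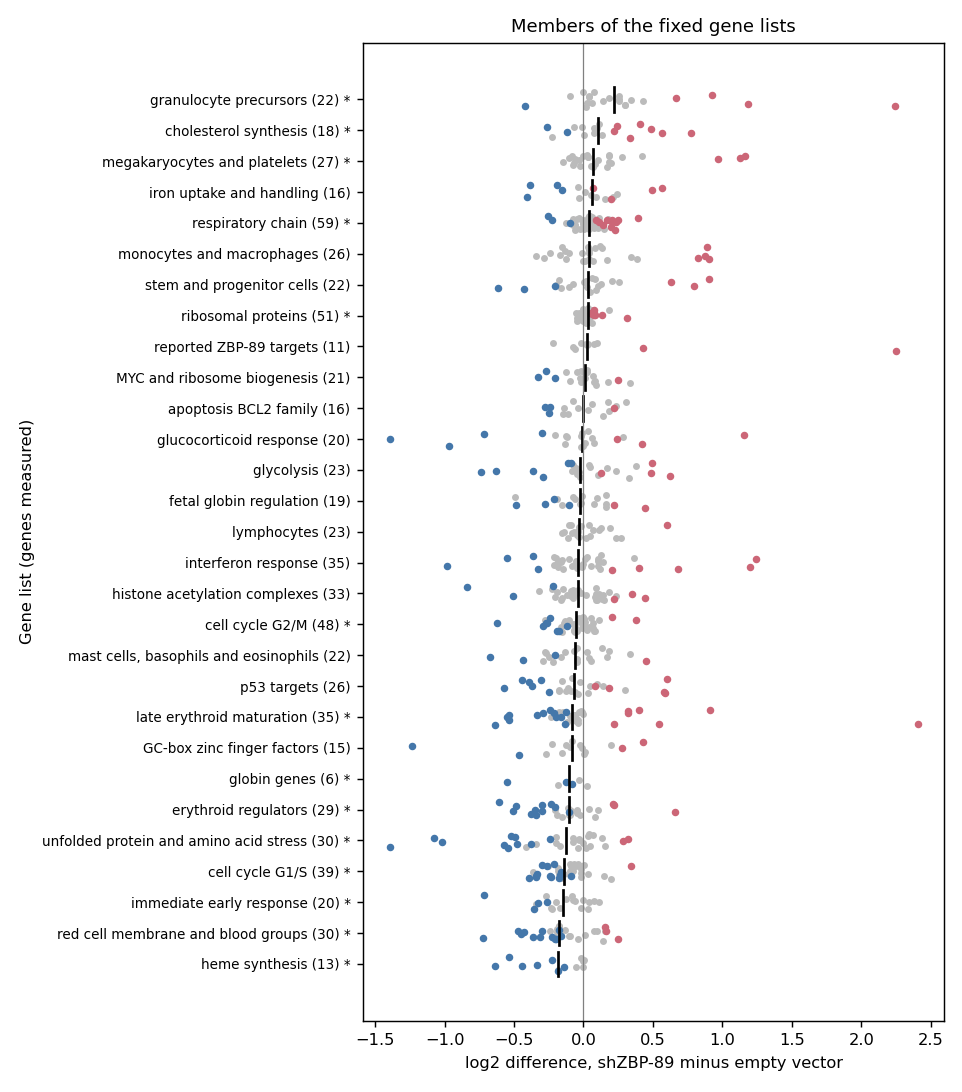
Log2 difference, shZBP-89 minus empty vector on the deposited scale, of each measured gene in 29 fixed gene lists; red and blue points are genes that rose or fell past the test over all genes, grey points did not pass, black bars are medians and stars mark an adjusted p under 0.05 in limma's camera with a preset correlation of 0.01. The medians of G1/S, heme synthesis and red cell membrane genes lie below 0, at −0.14, −0.18 and −0.18, and that of granulocyte precursor genes above 0, at 0.22, and the medians of all 5 lists that were higher in camera turn negative when arrays are scaled to the poly-A spike-ins.

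Of the 29 lists, 14 passed in camera with the preset correlation, 5 higher and 9 lower, and 0 passed with an estimated correlation (smallest adjusted p = 0.59). At an unadjusted p under 0.05, 0 lists passed with the estimated correlation. The simulated list shifted by 0.3 was not called with this setting either, so 0 calls do not show that the lists did not differ. Heme synthesis had an estimated correlation of −0.050. Its unadjusted camera p was 5.39e-05 with the preset and 0.0506 with the estimated correlation, so correlation between its genes was not what removed that call. The globin, immediate early and cholesterol synthesis lists also had negative estimated correlations (−0.083, −0.020 and −0.0054) and lost their calls. The other called lists had positive ones. With an estimated correlation camera works with the 2 residual degrees of freedom, which alone weakens the test of every list. A call lost in this setting thus does not show that gene correlation undid it. Limma's fry, which tests whether a list moved on balance in 1 direction and compares it with no other genes, called 1 list, cholesterol synthesis (adjusted p = 0.0398). Without the variance trend 9 lists passed, and the globin, late erythroid, G2/M, respiratory chain and ribosomal protein lists did not.

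The arrays of the groups also differed in their control probe sets, and this moved together with every gene group above. The signal of ACTB at the 3' end minus that at the 5' end, a sign of RNA integrity and labelling, was 1.13 ± 0.0468 on the log2 scale with empty vector and 1.45 ± 0.000665 with shZBP-89 (SD, n = 2). For GAPDH it was 0.447 ± 0.0269 and 0.636 ± 0.0277. Of the 24 probe sets for the poly-A spike-in RNAs of the bacterial genes dap, lys, phe and thr, 22 rose past the test, with a median log2 difference of 0.39. The 24 probe sets read the same few RNAs repeatedly and are not independent. The 12 of these in the array's r2 series, which served for the scaling, had a median of 0.41, and 11 passed. An exact permutation test of 2 arrays against 2 cannot give a two-sided p below 0.333, so the values of single control measures were not tested that way.

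**Figure D4:**
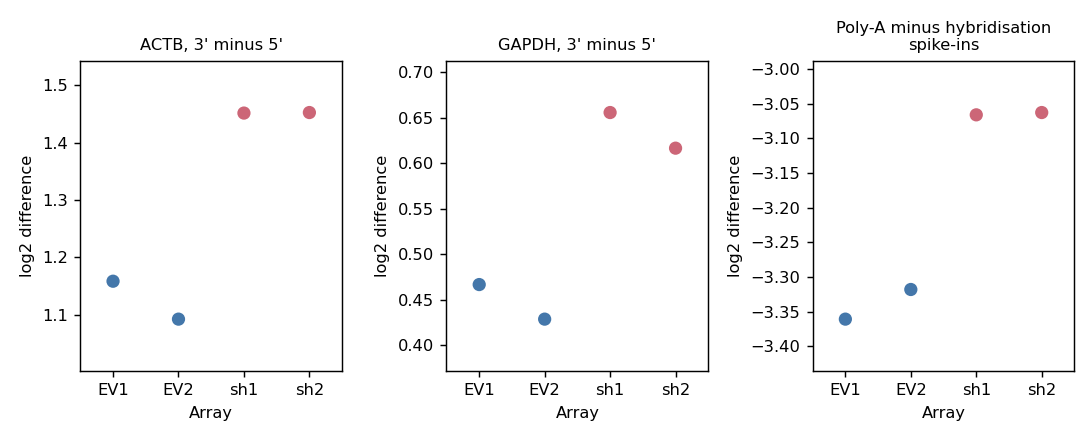
Control measures on each array (EV, empty vector; sh, shZBP-89; the digit is the replicate), as log2 differences of 3' minus 5' probe sets of ACTB and GAPDH and of the mean of poly-A minus the mean of hybridisation spike-in probe sets of the r2 series; points are arrays. ACTB averages 1.13 with empty vector and 1.45 with shZBP-89, and the groups do not overlap in any of the 3 measures.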

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

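All tests in this part were chosen after the values were seen. Outlying arrays were not looked for, since each group had 2.

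Measures outside the gene comparison differed between the groups. The 3' minus 5' difference of the ACTB control probe sets was 0.327 larger on the log2 scale with shZBP-89, and that of GAPDH 0.189 larger. The 24 poly-A spike-in probe sets had a median log2 difference of 0.39, and the 12 of the r2 series 0.41. Of the probe sets with no gene listed, 145 of 2108 changed (65 higher, 80 lower), and of those given several genes 167 of 1043 changed (82 higher, 85 lower), at an adjusted p under 0.05 in limma over all probe sets.

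The 5' signal of ACTB and GAPDH was lower on the shZBP-89 arrays, by log2 differences of −0.34 and −0.27 (adjusted p = 0.000101 and 7.75e-05 in limma over the control probe sets), against −0.01 and −0.08 at the 3' end. Lower RNA integrity or 5' labelling as the whole cause of the large rises stays open. The largest rise of a 3' control probe set was 0.22, and 159 genes rose past the test by more than 3 times that. This count cannot decide, since the 45 genes that rose 2-fold or more exceed that mark by their size alone. As a cause of falls, lower RNA integrity or 5' labelling stays open too. Of the genes that fell past the test, 42.6% (368 of 863) fell by no more than the ACTB 5' probe set, and the distance of each probe set from the 3' end was not used here. A change with the knockdown itself also stays open and was not tested.

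The poly-A spike-in RNAs, which are added to the RNA before labelling, read higher on the shZBP-89 arrays in all 24 probe sets, 22 of them past the test. These probe sets read the dap, lys, phe and thr RNAs repeatedly, so they are not independent results. Brighter hybridisation or scanning would raise the hybridisation spike-ins as much, but these had a median log2 difference of 0.14. In the r2 series the poly-A mean lay below the hybridisation mean on every array, by 0.28 less with shZBP-89, where the SD between replicates was 0.0215 (0.25 less, with an SD of 0.0213, over all 24 poly-A and 18 hybridisation probe sets). The compared probe sets differ in intensity, however. Hybridisation probe sets for bioB, at 766 to 1113 units with empty vector, rose by 0.18 to 0.23 in the r2 series. Those for cre, at 25985 and 29583 units, rose by 0.022 and 0.026. The lowest poly-A difference of the series, 0.237, lay next to the highest hybridisation difference, 0.233. Brighter hybridisation or scanning thus stays open as part of the rise. Less messenger RNA per unit of total RNA in the shZBP-89 cells and more spike-in RNA added to those samples cannot be told apart from the median difference of 0.41 in the r2 series, since the amounts added were not analysed here.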

How the results depend on the processing

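The crossed pairing and the spike-in scaling were chosen after seeing the data. ZNF148 stayed lower and past the test wherever it had a value, with log2 differences from −1.63 to −1.21; without shared probe sets (_x_at and _s_at) it had none. The count of changed genes, 1849 (986 higher, 863 lower), was 635 (382, 253) without the variance trend, 790 (443, 347) with a floor of 64, 1057 (558, 499) without shared probe sets, and 320 (179, 141) against a 1.2-fold difference. Median centring left 571 lower genes, and spike-in scaling gave 9516 (190, 9326). Of the 986 rises, 514 were smaller than the spike-in shift of 0.39. Leaving out 1 array, with the lone array assumed to vary like the other group, gave 683 to 4021 genes, 332 to 2205 higher and 319 to 1816 lower. The count was 683 without empty vector replicate 1, 735 without empty vector replicate 2, 4021 without shZBP-89 replicate 1 and 3122 without shZBP-89 replicate 2. In every one of these 4 fits 587 of the 1849 calls passed.

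Of the lists, 14 passed, against 9 without the trend, 9 with median centring, 7 without shared probe sets, 9 to 12 without 1 array (9 without shZBP-89 replicate 2), 0 with an estimated correlation and 1 in fry. The heme synthesis, red cell membrane, G1/S and granulocyte precursor lists passed in every camera fit with the preset correlation that tested them, 16 fits for the first 3 and 15 for the last. The late erythroid list passed in 1 of 16 such fits, the globin, megakaryocyte and G2/M lists in 10, the respiratory chain and ribosomal protein lists in 12, the regulator and cholesterol synthesis lists in 14, and the stress and immediate early lists in 15. Adjusted p rose to 0.107 for globin, 0.569 for megakaryocyte, 0.74 for G2/M, 0.689 for late erythroid, 0.738 for ribosomal protein, 0.71 for respiratory chain, 0.218 for regulator and 0.169 for cholesterol synthesis genes, and 0.2 for each of the stress and immediate early lists. ALAS2 was not followed over these fits. Among the other named genes and the called lists, these values turned sign: SMYD2 to 0.20, ATP5MC2 to −0.29 and the ribosomal protein median to −0.0095 without shared probe sets, and HBQ1, which did not pass, to −0.026 without shZBP-89 replicate 2 (−0.026 to 0.076 over the fits without 1 array). With spike-in scaling the medians turned for the granulocyte (−0.18), megakaryocyte (−0.32), cholesterol synthesis (−0.29), respiratory chain (−0.35) and ribosomal protein (−0.36) lists, and the values for UNG (−0.053), CTSG (−0.097), AZU1 (−0.14), EPB42 (−0.14), NDUFB2 (−0.14), FBL (−0.15), MYB (−0.17), ZNF281 (−0.20), RPL36 (−0.26), CDKN1A (−0.30) and HBQ1 (−0.37). The spike-in scaling shifts every gene by nearly the same amount; for the other differences the cause was not tested.

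Whether replicate numbers pair the arrays could not be settled. Same-numbered arrays deviated from their group means with a correlation of −0.14 across genes. The arrays of a group deviate by equal and opposite amounts, so the crossed pairing must give 0.14. This correlation thus cannot show whether the arrays are paired. The replicate block gave 2195 genes and 15 lists. The crossed block gave 2201 genes and 13 lists. Signal over background limits 87 changed genes whose dimmer group lay within the bacterial control readings.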

Other observations

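The tests of a cell mixture and of gene families named by symbol were chosen after the values were seen, and the mixture test replaced a permutation test on lists that held the pattern's own genes. Interferon response genes moved in both directions, with 5 of 35 higher and 4 lower (6 and 4 adjusted over the list alone; camera adjusted p = 0.954 in limma). BST2, which encodes tetherin, rose from 492 ± 10.7 to 1161 ± 80.2 units (SD, n = 2), IFI27 from 805 ± 18.5 to 1844 ± 47.5 units, and TRIM22 by 0.68 on the log2 scale, while RSAD2, which encodes viperin, fell from 300 ± 8.02 to 152 ± 11.0 units. Glycolysis genes split in the same way, with 4 of 23 higher and 6 lower (7 and 6 adjusted over the list alone; adjusted p = 0.954). ENO1, the enolase gene, fell from 6204 ± 57.3 to 3721 ± 52.7 units (SD, n = 2; its probe sets from −1.06 to −0.23 on the log2 scale) and the muscle type phosphofructokinase gene PFKM had a log2 difference of −0.63, while the platelet type gene PFKP rose by 0.49 and GPI by 0.49. Among p53 targets 5 of 26 rose, among them ZMAT3 by 0.60 and TP53I3 by 0.58, and 6 fell, among them SESN1 at −0.57 (5 and 6 adjusted over the list alone; adjusted p = 0.566). CDKN1A, the p21 gene, had 0.10 and did not pass, and MDM2 had −0.44 with other probe sets up to 0.23. Of 11 genes reported as ZBP-89 targets in other cells 2 rose, VIM at 2.25 and CDKN2A, which encodes p16 and p14ARF, at 0.43 (its 3 probe sets from 0.053 to 0.75), and 0 fell (2 and 0 adjusted over the list alone; adjusted p = 0.228).

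Of 33 genes of histone acetylation and deacetylation complexes 3 rose and 3 fell (4 and 4 adjusted over the list alone; camera adjusted p = 0.789 in limma), and the falls included KAT2B, which encodes the acetyltransferase PCAF, at −0.84 and TAF5L at −0.51, against TADA3 at 0.44 with another probe set at 0.016. Of 19 genes of fetal globin regulation 2 rose, MYB and HIC2, the latter by 0.45 (its probe sets from 0.060 to 0.53), and 4 fell, including BCL11A (3 and 6 adjusted over the list alone; adjusted p = 0.566). In iron handling 4 of 16 rose and 4 fell (5 and 4 adjusted over the list alone; adjusted p = 0.954), with the glutaredoxin gene GLRX5 at −0.41, the transferrin receptor gene TFRC at −0.19 (−0.099 with its other probe set) and CYBRD1 at 0.50. Of 20 glucocorticoid response genes 3 rose and 4 fell, among them KLF9 at −0.97 with another probe set at −0.066 (4 and 4 adjusted over the list alone; adjusted p = 0.566). Of 15 GC-box factors 2 rose and 2 fell, which were ZNF148 itself and KLF13 at −0.46 (2 and 2 adjusted over the list alone; adjusted p = 0.376). Of 16 BCL2 family genes 1 rose and 3 fell, among them BCL2L1, which encodes BCL-XL, at −0.27 with other probe sets up to −0.10 (1 and 4 adjusted over the list alone; adjusted p = 0.954). Of 21 MYC and ribosome biogenesis genes 1 rose, FBL at 0.25, and 3 fell (3 and 3 adjusted over the list alone; adjusted p = 0.954). The median and camera's direction had opposite signs for the lymphocyte, BCL2 family and interferon lists, and the glycolysis list had a median of −0.025 and a mean of 0.021. Among 81 families of genes sharing the start of their symbol, 1 passed in camera, RPL, with 10 of 36 genes higher (median 0.035, adjusted p = 0.00187, adjusted p = 0.997 with an estimated correlation). Of 235 ZNF genes 22 fell and 4 rose, with a median of −0.074 and adjusted p = 0.307.

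MPO, ELANE, PPBP, PF4, LYZ and the HLA class II genes HLA-DPA1 and HLA-DPB1 were higher while erythroid lists were lower. The smallest of these rises was the 0.83 of HLA-DPB1, and the genes were picked because they rose. A smaller share of erythroid cells need not raise the markers of every other cell type alike. It would do so only if erythroid cells lacked them and the other types kept their proportions. Tested were 10 mast cell, basophil and eosinophil markers on no other list that read above background by a factor of 2 or more. Their median log2 difference was 0.032 (SD 0.34 across markers), and CLC and TPSAB1, whose other probe sets reach −0.021, fell while CPA3 rose. As a set they did not rise like the genes above. The conditions for an equal rise were not tested, so a smaller share of erythroid cells stays open. More granulocyte precursor cells in the shZBP-89 cultures stay possible: AZU1 and CTSG had 0.25 and 0.30 and did not pass and PRTN3 fell by 0.42, a median of 0.25 over genes that went both ways at 111 to 193 units with shZBP-89, too near background to decide. Altered expression of these genes within erythroid progenitors, from less ZBP-89 or from other effects of the hairpin, was not tested and stays open.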
